A study of Mus musculus with 16 samples.

How the data were processed

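RNA from kidney and liver of 3 male wildtype C3HeB/FeJ mice was hybridised to 16 cDNA arrays with 20419 probes. Per the labels, the left kidney or the dorsal lobe of the liver was used, 20 µg of total RNA was labelled indirectly with Cy3 or Cy5, and each single sample was set against a pool of 5 animals of the other organ. Slides were scanned with a GenePix 4000A scanner. Per the labels' protocols, GenePix Pro 3.0 gave mean intensities with the local background subtracted, and ratios were normalised to a median of 1 on each array. The deposited values are log2 ratios of both channels. The labels do not state the base, which was read from the values: of 144 spacings between the most frequent values, 141 were the log2 of a ratio of whole numbers up to 10 within 1e-04, against 0 for the natural logarithm and 16 for log10. Which dye was used for which sample on an array is not stated, and raw intensities were not used.

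The direction of the ratio was set from markers. Titles name the single sample before the pool, but the deposited values had the opposite direction on both kinds of arrays. Of 27 hepatocyte genes, 27 had a positive mean on the kidney arrays and 26 a negative mean on the liver arrays, with medians of 5.55 and -5.66, and the proximal tubule list had medians of -2.95 and 3.11. The collecting duct list had -0.58 and 0.50. As deposited, the list of the loop of Henle and distal tubule went against this reading, with 10 of 14 members positive on the kidney arrays and medians of 0.32 and -0.27. These means include the arrays of mouse 2, whose medians lay away from 0. Turned to kidney over liver, the median of this list was -0.28, but 0.17 after centring each array and 0.21 with mouse 2 aligned by signal. The values were therefore read as pool over single sample and turned to kidney over liver. Exchanged organs in all titles would give the same kidney and liver reading, while the title order would exchange every kidney and liver word and leave sizes and tests as they are. The choice followed the data, and the lists it used are not independent evidence of direction.

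The labels' median of 1 held on the 10 arrays of mice 1 and 3, whose absolute median log2 ratio was at most 0.00267. On the 6 arrays of mouse 2 it did not, with deposited medians between 1.19 and 1.49 on the kidney arrays and between -1.35 and -1.32 on the liver arrays. Values were used as deposited, and centring was among the alternatives. Signal was judged by the share of values that recur exactly on an array, taken as a sign of small whole-number intensities. The share is read from the ratios under test. A ratio far from most others can also fail to recur, so large organ differences can fall among bright probes at any intensity. A probe was bright with a share of at most 0.1 and dim with a share over 0.5, over at least 8 of the 10 arrays of mice 1 and 3, which gave 2967 bright and 7126 dim probes.

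Gene names came from the probe annotation provided for this platform, of which 11723 probes had 1 symbol, 806 several and 7890 none. Of the first, 11590 matched a RefSeq gene and 133 kept the platform's name. Probes of a gene were averaged, which gave 9669 genes. Of 1523 genes with more than 1 tested probe, 8 had probes called in opposite directions.

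Hybridisations of the same mouse and organ were averaged, and limma 3.58.1 in R 4.3.3 was fitted to the 6 averages, with a mean for the organ difference and a term for the array kind, on probes with values in at least 2 mice per organ. The median SD was 0.271 between hybridisations and 0.788 between mice within an organ, and 0.207 and 0.359 for bright probes. Mice were compared within an organ by limma's moderated F on single arrays. All p-values are two-sided and adjusted by Benjamini-Hochberg at 0.05. The pools give no estimate of spread. Figures were drawn with matplotlib 3.10.9.

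Mouse numbers identify the same animals on both kinds of arrays, per the labels. Over 14688 probes, deviations of a mouse from the others on the scale of single sample over pool correlated between its kidney and liver arrays at -0.591, -0.795 and -0.585 for mice 1, 2 and 3. A fit with the mouse number as a replicate block on that scale was an alternative. The main fit for kidney against liver had no block and took the kidney and liver averages of a mouse as independent. As these deviations are positively correlated as kidney over liver, its SE and p-values tend to be too small. Correlations are across probes, which are not independent replicates.

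Genes were named by a rule fixed, together with the lists and most alternatives, before the data were examined: the 12 genes with the largest change in each direction among those past the threshold with the same sign in every average, the 3 called members with the largest change in each list together with called members against its median, and the 6 genes with the lowest adjusted p between mice in each organ. Ties in the last, which the rule did not cover, were broken by the largest F. Other genes in the texts were chosen after their values were seen. The 30 lists hold 897 genes, of which 526 were tested, 69 were higher in kidney and 128 in liver. They cover hepatocyte plasma proteins, complement and coagulation, hepatic cytochrome P450, urea cycle and amino acids, bile acids, lipid synthesis, fatty acid oxidation, gluconeogenesis, phase II enzymes, growth hormone dependent genes, acute phase, proximal tubule, loop of Henle, collecting duct, glomerulus, androgen response, renal metabolism, oxidative phosphorylation, tricarboxylic acid cycle, ribosome, endoplasmic reticulum, clock, stress response, blood, leukocytes, adrenal cortex, pancreas and intestine, adipose tissue and muscle, bile duct and stellate cells, and reference genes. Lists were tested with camera at a preset correlation of 0.01 and with an estimated one. Camera used only genes with a value in every average of the fit. Its tests can therefore hold fewer genes than the counts beside them, such as 8 of 15 for adipose tissue and muscle and 15 of 21 for leukocytes. Ucp1, Krt18, Cd79b, Amy2 and Hsp90aa1 were not in the main list tests.

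Each step was tested on simulated data with 50 probes changed at each of 1, 2, 3 and 4 on the log2 scale. For kidney against liver on 18670 probes 14%, 66%, 82% and 98% were recovered, with 3 unchanged probes called. Between mice the shares were 22%, 74%, 96% and 94% for kidney (14850 probes, 4 unchanged called) and 52%, 88%, 94% and 100% for liver (18449 probes, 13 unchanged called). For lists, 2 of 2 changed by 1 on 9047 genes were recovered, with 0 others called. Values were drawn independently for each probe or gene and each average. Deviations shared by both array kinds, a common offset of mouse 2 and correlation between genes were left out. The few false calls therefore do not measure the error of these tests on the real data. The alternatives were other scalings, filters, variance models, treatments of hybridisations, blocks, single array kinds and each mouse or hybridisation left out. Alignment of mouse 2 to the others within classes of signal, bright probes alone, blocks on kidney over liver and all blocks for the comparison of both array kinds were added after seeing the data.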

Results

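Gene expression in kidney and liver of male wildtype C3HeB/FeJ mice, an inbred laboratory strain, was measured on 16 cDNA microarrays with 2 colours. Each array held the RNA of an organ of a single mouse together with a pool from 5 animals of the opposite organ. On 7 arrays the kidney of mouse 1, 2 or 3 was set against a pool of 5 livers (3, 3 and 1 arrays), and on 9 arrays the liver of the same mice was set against a pool of 5 kidneys (3 arrays each). The mice were 105 ± 5 days old. Of 20419 probes, between 15480 and 19430 had a value on an array, with a median of 17840. Arrays of the same mouse and organ repeat the same RNA, so they were averaged (n = 3 mice per organ). Kidney and liver averages of the same mouse then entered the main fit as independent values. On the scale of single sample over pool, their deviations correlated at -0.591, -0.795 and -0.585 for mice 1, 2 and 3. As kidney over liver these correlations are positive. The main fit left this out, so its SE and p-values for kidney against liver tend to be too small. With the mouse number as a replicate block on the scale of sample over pool, 966 probes passed in place of 2358. The SE of Pgk1, for example, was then 0.454 in place of 0.206. SE and calls below are from the main fit unless another is named. The number of mice limits the precision.

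The comparison asked which genes differ in RNA level between kidney and liver. All signed values below are log2 ratios of kidney over liver. The labels do not state which channel was the numerator, and the titles name the single mouse before the pool. Read in that order, albumin (Alb) would be a kidney transcript. Its mean deposited value was 8.44 on the kidney arrays and -7.57 on the liver arrays, while that of the kidney transcript Kap was -5.77 and 6.08. The direction was therefore taken from these textbook markers, as pool over single mouse, and the sign was turned accordingly. This opposes the order of the titles. With the order of the titles, every "kidney" and "liver" of the calls below would be exchanged, with the same sizes and tests. The marker lists used for this choice are not independent evidence of direction.

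Liver excess was led by genes of secreted plasma proteins. The 12 genes with the largest liver excess were 149-fold to 258-fold higher in liver. They were Ahsg (fetuin-A; -8.01, SE 0.25), Alb (-7.89, SE 0.43), Mup3 (major urinary protein; -7.89, SE 0.27), Fgb (fibrinogen beta chain; -7.81, SE 0.21), Apoc1 (apolipoprotein; -7.80, SE 0.22), Hp (haptoglobin; -7.70, SE 0.24), Mug-ps1 (-7.66, SE 0.22), Hpx (hemopexin; -7.60, SE 0.21), Mup9 (-7.49, SE 0.41), Plg (plasminogen; -7.31, SE 0.23), Csf2ra (-7.24, SE 0.25) and Vtn (vitronectin; -7.21, SE 0.23). Kidney excess was smaller in size, and the 12 leading genes were 35.4-fold to 72.8-fold higher in kidney. They were Akr1c21 (an aldo-keto reductase; 6.19, SE 0.31), Kap (kidney androgen-regulated protein; 6.05, SE 0.28), Cyp4b1 (5.96, SE 0.27), Dnase1 (5.83, SE 0.30), Ndrg1 (5.69, SE 0.26), Map1lc3b (5.60, SE 0.33), Laptm4b (5.47, SE 0.27), Rbm42 (5.42, SE 0.28), Miox (myo-inositol oxygenase; 5.18, SE 0.25), Cubn (cubilin, an endocytic receptor; 5.16, SE 0.31), Slc13a1 (a sodium-sulfate cotransporter; 5.15, SE 0.26) and Cdh16 (kidney-specific cadherin; 5.15, SE 0.35). Each of these 24 genes had the same sign in all 6 averages of a mouse and organ, and the adjusted p ranged from 3.26e-07 to 2.14e-05 (limma, Benjamini-Hochberg). Each is represented by 1 probe. A cDNA probe can also bind transcripts of near-identical family members, as among the major urinary proteins, so values of Mup3 and Mup9 are not specific to either gene.

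**Figure D1:**
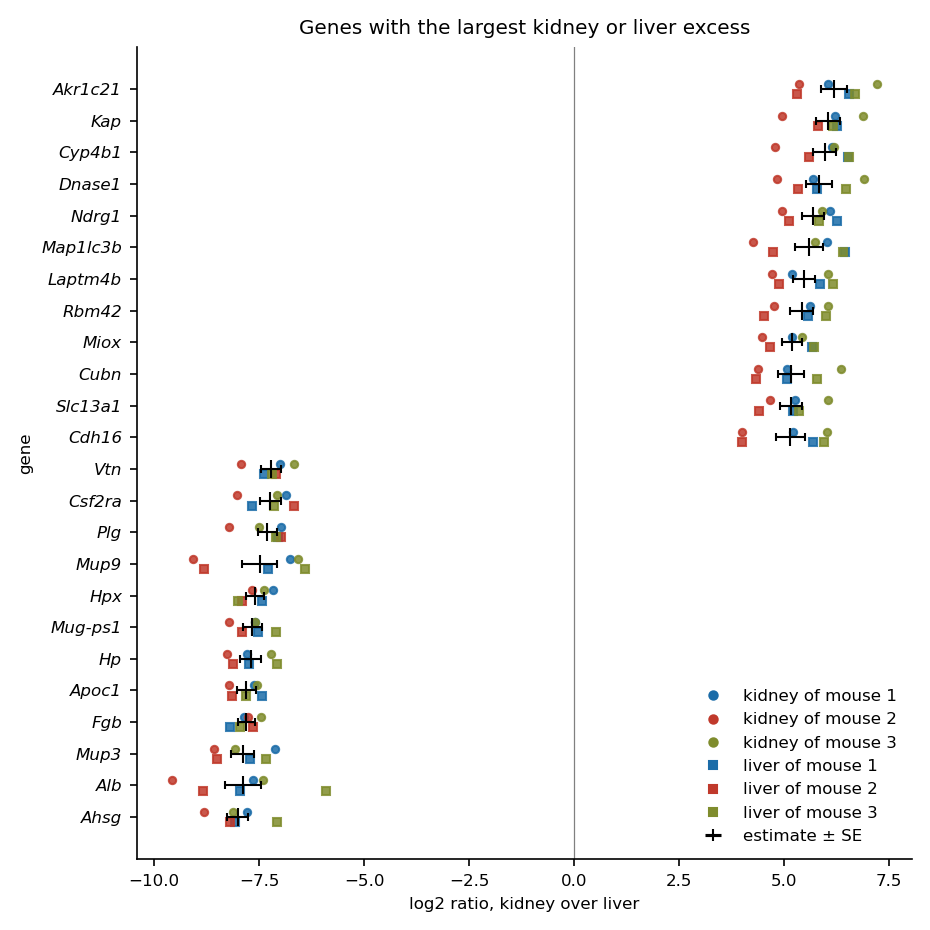
Log2 ratio of kidney over liver (horizontal axis) of the 12 genes with the largest excess in each organ (vertical axis). Circles are averages of kidney arrays, squares averages of liver arrays, coloured by mouse, and black bars are the limma estimate with its SE over 6 averages. All points of the upper 12 genes lie above 0 and all points of the lower 12 below 0.

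At the level of genes, 9047 were tested and 1306 passed (limma, Benjamini-Hochberg adjusted p under 0.05), 503 higher in kidney and 803 higher in liver. Of 18670 probes tested, 2358 passed, 967 higher in kidney and 1391 higher in liver. This split changed with the treatment of the 6 arrays of mouse 2. Their median log2 ratio lay between -1.49 and -1.19, while those of the other 10 arrays lay within 0.003 of 0, and the median estimate over all probes was -0.53. After centring every array on its median, which moved the median estimate to -0.06, 5445 probes passed, 3328 higher in kidney and 2117 in liver, and without mouse 2 the numbers were 4873 of 14864, 2747 and 2126. Quantile normalization gave 13609, 1980 higher in kidney and 11629 in liver, and the mouse number as a replicate block on kidney over liver 15400, 2768 and 12632. Trend and robust variances, with mouse 2 as deposited, gave 2866, 1506 higher in kidney and 1360 in liver. The share of each organ thus depended on the treatment. Without mouse 1 in both organs 700 probes passed, and without mouse 3 799. With the mouse number as a replicate block on the scale of sample over pool, 966 probes passed, 427 higher in kidney and 539 in liver. The 2967 probes with bright signal held 1419 of the 2358 calls, with 769 higher in kidney, and tested alone gave 2141 calls, 1226 higher in kidney. Bright probes were picked by how seldom their ratios recur, which can favour large organ differences. Their share of the calls is therefore not a measure of signal alone.

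**Figure D2:**
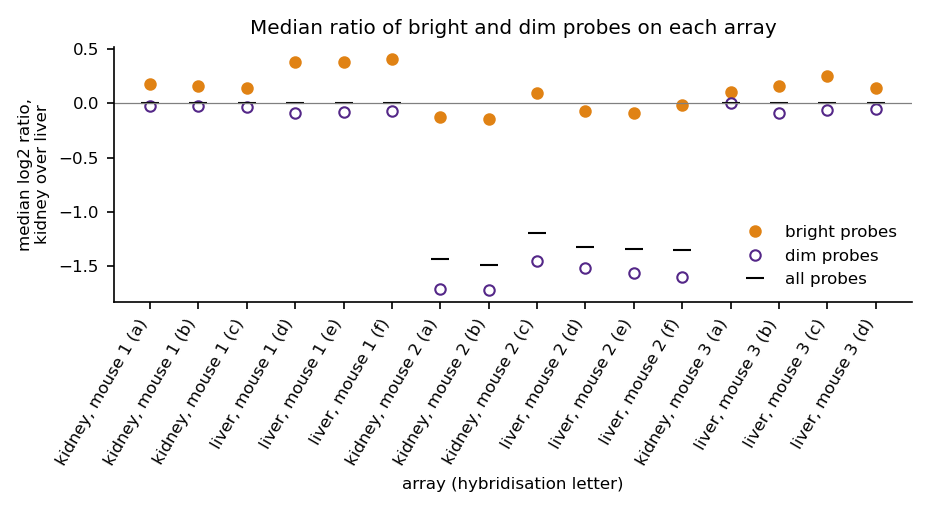
Median log2 ratio of kidney over liver on each of the 16 arrays (vertical axis; arrays on the horizontal axis, with mouse and hybridisation letter), for all probes (bars), bright probes (filled circles) and dim probes (open circles). On the 6 arrays of mouse 2 the median of the dim probes lies between -1.72 and -1.45 and that of the bright probes between -0.15 and 0.09.

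Secreted products of hepatocytes were higher in liver as a group. Of 27 measured genes for plasma proteins, 22 were higher in liver and none in kidney (23 adjusted over the list alone), with a median of -5.57. Besides the leading genes these included Rbp4 (retinol-binding protein; -7.08), Itih4 (-6.62) and Serpina1b (alpha-1-antitrypsin; -6.58). The list's camera test gave an adjusted p of 3.48e-20, and 0.108 as adjusted p with an estimated correlation. Camera used only genes with a value in every average, 25 of the 27 here, so list tests can hold fewer genes than the counts. Of 23 genes of complement and coagulation, 17 were higher in liver and none in kidney (19 adjusted over the list alone), led by Plg, F2 (prothrombin; -7.17, SE 0.21) and Serpinc1 (antithrombin; -6.87, SE 0.21). Its adjusted p was 7.12e-11 by camera, and the adjusted p with an estimated correlation was 0.115. After centring 17 of these genes were higher in liver and 1 in kidney, and with mouse 2 aligned by signal 19 and 2. Of 12 acute phase and interferon genes, 7 were higher in liver (8 adjusted over the list alone). Fgb, Hp and Orm1 (orosomucoid; -5.85) led the list, while the interferon-induced Ifit3 (-0.44) and Oas1a (-0.68) did not pass. Its camera adjusted p was 1.35e-05, and 0.114 as adjusted p with an estimated correlation.

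Of 25 genes of the urea cycle and amino acid catabolism, 13 were higher in liver and none in kidney (14 adjusted over the list alone). Bhmt (betaine-homocysteine methyltransferase; -7.05, SE 0.21), Mat1a (-6.82, SE 0.22), Tat (tyrosine aminotransferase; -6.80, SE 0.20) and Arg1 (arginase 1; -5.34, SE 0.32) led it, whereas Ass1, which acts in both organs, was at -0.24 (SE 0.20) and did not pass. Camera gave an adjusted p of 4.35e-06, and 0.108 as adjusted p with an estimated correlation. After centring 12 of these genes were higher in liver and 2 in kidney, and with mouse 2 aligned by signal 14 and 2. Of 12 hepatic cytochrome P450 genes, 7 were higher in liver (7 adjusted over the list alone), among them Cyp3a11 (-6.78), Cyp2f2 (-4.92) and Cyp2d9 (-3.72). This list had an adjusted p of 0.0001, and 0.108 as adjusted p with an estimated correlation. After centring 7 of its genes were higher in liver and 1 in kidney, and with mouse 2 aligned by signal also 7 and 1. For bile acid synthesis and transport, 8 of 11 genes were higher in liver (8 adjusted over the list alone), including the bile salt export pump Abcb11 (-5.68), Slc27a5 (-4.12) and Cyp27a1 (-3.51), with adjusted p of 6.21e-05, and 0.108 as adjusted p with an estimated correlation. Of 20 genes of phase II conjugation and antioxidant defence, 11 were higher in liver and 1 in kidney (13 and 1 adjusted over the list alone). Sult1a1 (-3.10), Ephx1 (-2.59) and Ugt2b36 (-2.16) fell on the liver side and Nat8 (1.82) on the kidney side. After centring 7 were higher in liver and 2 in kidney, and with mouse 2 aligned 12 and 2. Its adjusted p was 0.00814, but 0.184 after quantile normalization, 0.114 without mouse 1, 0.143 without mouse 3, 0.121 with the mouse number as a replicate block on kidney over liver and between 7.14e-05 and 0.184 over the alternatives with the preset correlation. The adjusted p with an estimated correlation was 0.333.

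Of 10 male-biased or growth hormone dependent liver genes, 9 were higher in liver (9 adjusted over the list alone). Next to Mup3, these were led by Nudt7 (-5.01, SE 0.23) and Igfbp2 (-4.13, SE 0.20). Igf1, the growth factor made in liver under growth hormone, was at -3.88 (SE 0.26). For this list the adjusted p was 1.77e-08, and 0.108 as adjusted p with an estimated correlation. Genes of lipid and sugar metabolism went both ways. Of 18 genes of cholesterol and fatty acid synthesis, 6 were higher in liver, led by Scd1 (stearoyl-CoA desaturase; -4.10), Dhcr7 (-2.62) and Fasn (-2.33), and Me1 (malic enzyme; 2.08) was higher in kidney (6 and 1 adjusted over the list alone). Of 20 genes of fatty acid oxidation and ketogenesis, Fabp1 (-6.89), Acaa2 (-3.11) and 2 others were higher in liver, and Hadha (1.96) and Hadh (0.73) in kidney (4 and 2 adjusted over the list alone). Of 14 genes of gluconeogenesis and fructose metabolism, Pygl (liver glycogen phosphorylase; -2.53), Pklr (-1.11) and Ldhb (-0.89) were higher in liver and Pgk1 (1.12) in kidney (4 and 2 adjusted over the list alone). These 3 lists did not pass as lists, with adjusted p of 0.244, 0.949 and 0.949. Their medians were -0.68, -0.40 and -0.32 as deposited and -0.23, 0.05 and 0.14 after centring, when 2, 4 and 4 genes were higher in kidney and 6, 3 and 2 in liver.

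Proximal tubule genes were higher in kidney. Of 31 measured, 21 were higher in kidney and 1 in liver (23 and 4 adjusted over the list alone), with a median of 3.03. Behind Kap, Miox and Cubn came carriers of the tubule membranes, such as the organic anion transporters Slc22a8 (4.92, SE 0.36) and Slc22a6 (4.22, SE 0.26), the organic cation transporter Slc22a2 (4.56, SE 0.28) and the amino acid transporter Slc6a18 (4.28, SE 0.29). The receptor Lrp2 (megalin) was at 3.86 (SE 0.28). Mep1a went the other way (-1.47, SE 0.24). It lost its call after centring (-1.02, adjusted p 0.0544, limma, Benjamini-Hochberg), on kidney arrays alone and without mouse 1 or mouse 3. After centring 24 genes of the list were higher in kidney and 0 in liver. With mouse 2 aligned by signal the numbers were 24 and 2, and Mep1a stayed called (-1.35, adjusted p 0.000688, limma, Benjamini-Hochberg). The list's adjusted p was 1.96e-23, and 0.114 as adjusted p with an estimated correlation. In the collecting duct list, 7 of 20 genes were higher in kidney and 2 in liver (8 and 3 adjusted over the list alone). The proton pump subunit Atp6v1g3 (3.27), the water channel Aqp2 (2.86) and pendrin Slc26a4 (2.54) were higher in kidney, and Krt18 (-1.87) and Ldhb (-0.89) in liver. After centring the numbers were 11 and 2, and with mouse 2 aligned 11 and 3. The adjusted p was 2.53e-05, and 0.394 as adjusted p with an estimated correlation. Of 14 genes of the loop of Henle and distal tubule, Cdh16 and Umod (uromodulin; 3.87, SE 0.20) were higher in kidney and Fxyd2 (-1.34, SE 0.32) in liver (2 and 2 adjusted over the list alone). After centring the numbers were 4 and 3, as with mouse 2 aligned. Fxyd2 is dim, with 55.6% recurring values, and was lower in mouse 2 (-2.465 and -2.17) than in mice 1 and 3 (-1.323 to -0.5258). That list did not pass (adjusted p 0.316), with a median of -0.28, which was 0.17 after centring, and a mean of 0.32.

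Genes of the glomerulus and renal stroma included 4 of 20 higher in kidney and 1 in liver (4 and 1 adjusted over the list alone). The podocyte genes Synpo (synaptopodin; 3.06, SE 0.21) and Podxl (podocalyxin; 2.40, SE 0.35) and the collagen IV chains Col4a2 (1.58) and Col4a1 (1.49) were higher in kidney, and Ehd3 (-1.14) in liver. After centring 9 were higher in kidney and 1 in liver, and with mouse 2 aligned 11 and 1. Camera gave an adjusted p of 0.000715, and 0.653 as adjusted p with an estimated correlation. Of 22 renal metabolism and transport genes, 9 were higher in kidney and 4 in liver (9 and 5 adjusted over the list alone). Car12 (a carbonic anhydrase; 4.05) and Klk1 (kallikrein 1; 3.13) were among the first, and Clu (clusterin; -3.59) among the second. After centring the numbers were 12 and 2, and with mouse 2 aligned 12 and 4. The adjusted p was 0.000199, and 0.394 as adjusted p with an estimated correlation. Of 18 genes of the tricarboxylic acid cycle, 3 were higher in kidney and none in liver, namely Pdha1 (1.70), Mdh1 (1.25) and Sdhd (0.85) (4 and none adjusted over the list alone). After centring, 12 were higher in kidney and 0 in liver, and with mouse 2 aligned by signal 11 and 1. This list had an adjusted p of 0.000576, and 0.333 as adjusted p with an estimated correlation. Of 12 genes that respond to androgen in kidney, Akr1c21, Kap, Cyp4b1, Nat8 and Cndp2 were higher in kidney and Cyp2d9, Serpinf2 and Adh1 in liver (5 and 3 adjusted over the list alone). Its median was -0.11, and 0.34 after centring, and its mean 1.14. The adjusted p was 0.00602 for kidney excess, but 0.159 with arrays scaled to one spread, 0.373 without mouse 2 and 0.232 with mouse 2 aligned by signal (8.32e-05 to 0.373 over the alternatives with the preset correlation), and 0.116 as adjusted p with an estimated correlation. The 2 probes of Cndp2 disagreed, at 3.91 and -1.76.

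**Figure D3:**
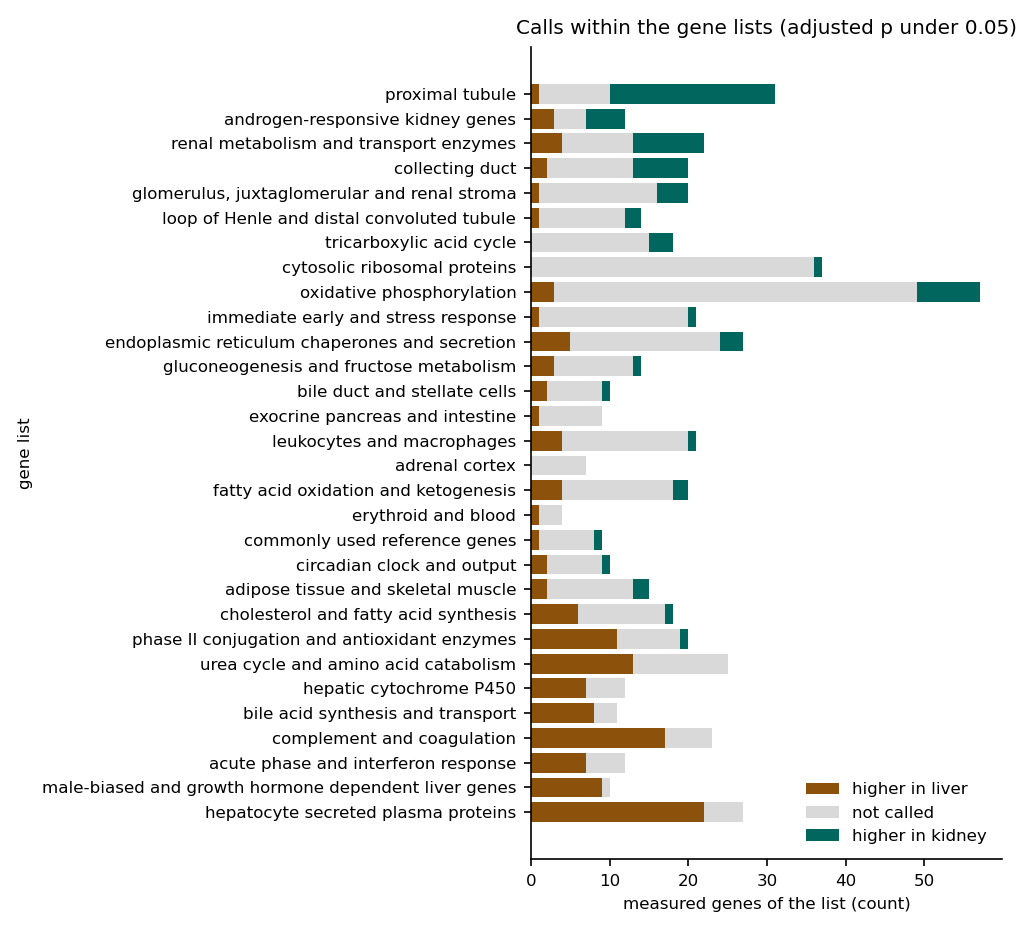
Number of measured genes (horizontal axis) in each of the 30 gene lists (vertical axis, ordered by mean ratio) that were higher in liver, not called or higher in kidney at an adjusted p under 0.05. Hepatocyte plasma proteins hold 22 genes higher in liver of 27 and proximal tubule 21 higher in kidney of 31.

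Of 57 measured subunits of oxidative phosphorylation, 8 were higher in kidney and 3 in liver (9 and 4 adjusted over the list alone), among them Cox4i1 (1.38, SE 0.21), Atp5pb (1.16, SE 0.24) and Ndufa2 (1.12, SE 0.20). The list did not pass (camera adjusted p 0.0768), but it did in 3 of 15 alternatives with the preset correlation, among them without mouse 3 in both organs (adjusted p 0.0279). The adjusted p ranged from 0.0279 to 0.576 over these alternatives, and was 0.981 with an estimated correlation. After centring, 15 were higher in kidney and 3 in liver, and with mouse 2 aligned 15 and 6. Its median was -0.25 as deposited and 0.20 after centring, which moves all genes of an array alike, and camera tested it toward kidney in each of 15 alternatives. Of 37 cytosolic ribosomal proteins, 1 was higher in kidney (Rpl15, 1.43, SE 0.32; none adjusted over the list alone), 6 after centring and 7 with mouse 2 aligned by signal, with an adjusted p of 0.316 for the list, which was 0.0345 without mouse 3 and up to 0.972 in the other settings with the preset correlation, and 0.981 with an estimated one. Their median of -0.17 became 0.28 after centring. For endoplasmic reticulum chaperones and secretion, 3 of 27 were higher in kidney, including Rpn1 (1.64) and Xbp1 (1.59), and 5 in liver (3 and 10 adjusted over the list alone; adjusted p 0.949 for the list), with a median of -0.38 that was 0.07 after centring. After centring 5 were higher in kidney and 3 in liver, and with mouse 2 aligned 6 and 10. Because camera sets a list against all other genes, whose median lay below 0, several lists with a median below 0 were tested toward kidney.

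Of the 103 genes named by the fixed rules, 23 lost their call with the mouse number as a replicate block on the scale of sample over pool, with adjusted p between 0.0661 and 0.324 (limma, Benjamini-Hochberg). From those named above, these were Pklr, Ldhb, Pgk1, Hadh, Mdh1, Sdhd, Ehd3, Cndp2, Atp5pb and Ndufa2. With the block on kidney over liver, 103 of 103 kept their call. That block takes differences between the mice out of the error term, and 15400 probes passed with it. Calls kept there therefore do not show replication over mice. After centring, Mep1a, Ldhb and Glud1 lost their call, while with mouse 2 aligned by signal 103 of 103 kept it. Over up to 23 alternatives, mostly those with a mouse or an array kind left out, Hadh lost its call in 13, Ldhb in 12, Sdhd in 10, Pklr and Cndp2 in 9 each, Glud1 in 8, Rpl15 in 7, Atp5pb in 6, Rpn1, Fxyd2 and Ehd3 in 5 each, and Mep1a, Pgk1, Mdh1 and Ndufa2 in 4 each. Cox4i1 lost it in 3, Col4a2 in 2, and Krt18, Pdha1 and Xbp1 in 1 each. Fxyd2 and Pklr are dim, with 55.6% and 66.7% recurring values. With mouse 2 aligned by signal they were at -0.85 and -0.61, both still called. No named gene changed its sign under any of the alternatives tried. As all 103 had the same sign in every measured average, settings that only left out or weighted averages could not change it. The 14 lists that passed also did so with the block on the scale of sample over pool, while 13 passed with the block on kidney over liver.

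The kidney arrays and the liver arrays were compared with each other, since each kind carries the single mouse in the opposite place of the ratio. In the fit without pairing, limma called 0 of 18670 probes (Benjamini-Hochberg adjusted p under 0.05), and 46, or 0.246%, had an unadjusted p under 0.05. That fit leaves out that deviations of a mouse repeat between its kidney and liver arrays. With the mouse number as a replicate block on kidney over liver, 18 probes passed and 1559 had an unadjusted p under 0.05, and with mouse 2 also aligned by signal 33 and 1920. On the scale of sample over pool the block gave 5 and 31. Among genes the same count was 0 of 9047, with 16 at an unadjusted p under 0.05. Ahsg was at -8.24 ± 0.52 (SD, n = 3 mice) on the kidney arrays and -7.79 ± 0.61 (SD, n = 3) on the liver arrays, and Kap at 6.01 ± 0.98 and 6.08 ± 0.25. The median absolute size of the difference term was 0.0945 and its 95th percentile was 0.314. Data were simulated with the spread of these arrays but independent averages, and 50 of 18670 probes were changed at each size. Changes of 1, 2, 3 and 4 on the log2 scale were recovered for 12%, 64%, 82% and 98% of them. The fit without pairing thus missed most simulated differences of 1. If each dye always went with the same organ, a dye effect would remain in the ratio, since it would not differ between both kinds.

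The mice were compared within each organ on single arrays, where repeated hybridisations give the spread. These p-values speak of the RNA and arrays of these 3 mice. On the kidney arrays, 10967 of 14850 probes differed between the mice (limma moderated F, Benjamini-Hochberg), and 293 genes shared the lowest adjusted p (6.71e-05), of which 2 were also called between mice 1 and 3 alone. The 6 with the largest F among them were Snx18, Sec14l2, Tcap, Top2a, Pdia2 and Tmem238. Snx18 was at -1.61 ± 0.12 (SD, 3 arrays) in mouse 1, -3.51 ± 0.13 (SD, 3 arrays) in mouse 2 and 0.48 (1 array) in mouse 3, and Tmem238 at -1.81 ± 0.01, -3.38 ± 0.12 and 0.31. Top2a, a topoisomerase of dividing cells, was at 1.54 ± 0.20, -1.89 ± 0.15 and 0.29. With mouse 2 aligned by signal, its value for Top2a was -0.70, that for Tcap -1.25 in place of -2.24 and that for Pdia2 -1.39 in place of -2.38, while Snx18 (-3.36) and Tmem238 (-3.22) changed little. Sec14l2 was at -4.42 ± 0.32, -4.81 ± 0.15 and -9.14, and rested on the single array of mouse 3, without which it lost its call. Between mice 1 and 3 only, 3 of 14453 probes differed, with 1797 at an unadjusted p under 0.05.

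On the liver arrays, 15870 of 18449 probes differed between the mice, and 197 of 18828 between mice 1 and 3 only (limma, Benjamini-Hochberg), with 4039 at an unadjusted p under 0.05. Expressed as liver over kidney, Tmem238 had the lowest adjusted p (2.59e-06) and was at 1.73 ± 0.13 (SD, 3 arrays) in mouse 1, 3.08 ± 0.06 in mouse 2 and -0.70 ± 0.09 in mouse 3. It still differed between mice 1 and 3 (adjusted p 0.00235, limma, Benjamini-Hochberg). Turned to kidney over liver, its values have the same signs and order of mice as on the kidney arrays (-1.81, -3.38 and 0.31). The difference is thus not particular to the liver arrays. Next, 15 genes shared an adjusted p of 1.61e-05, and the 5 with the largest F among them, Zfp385a, Irf4, Ten1, Zfp322a and Slc5a4b, had mouse 2 apart from the others. Irf4, a transcription factor of lymphocytes, was at -0.67 ± 0.15, 1.87 ± 0.11 and -0.28 ± 0.03 and Zfp385a at 0.66 ± 0.19, 2.89 ± 0.05 and -0.06 ± 0.16. With mouse 2 aligned by signal, its values fell to 0.63 for Irf4, 1.48 for Zfp385a, 0.95 for Ten1, 0.88 for Zfp322a and 0.40 for Slc5a4b, against 2.75 for Tmem238. These 5 were not called between mice 1 and 3, with adjusted p from 0.0855 to 0.769, but 2 of the 15 were, Mxi1 (adjusted p 0.00235) and D11Wsu47e (adjusted p 0.0159; limma, Benjamini-Hochberg), which were named after their values were seen. The counts were lower with other treatments of mouse 2: after centring the arrays, 7115 probes differed on the kidney arrays and 7133 on the liver arrays, and with mouse 2 aligned by signal 4871 and 5850.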

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

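The tests on the dim probes of mouse 2, on animals against constant pools and on other splits of the samples were chosen only after the result was seen. Single arrays stood apart from the others of their kind for 10 of 227 combinations of a gene and array kind, where about 11 are due to chance at 1 in 20, and for 0 of 14 measures of whole arrays. The test looks for an isolated array, so it could not flag the arrays of mouse 2, whose medians lay apart together. The 14 measures hold the median ratio in both signs. As kidney over liver, Plg was at -9.31 on the first kidney array of mouse 2 (next -7.81) and Hadha at 2.01 on the same array (next 1.71). Mat1a was at -6.04 on the first kidney array of mouse 1 (next -6.68). Orm1 was at -7.05 (next -5.74) and Sec14l2 at -9.14 (next -4.99) on the kidney array of mouse 3. On liver arrays, Sult1a1 was at -3.41 (next -3.07) and Cndp2 at 4.77 (next 2.08) on array d of mouse 3, Cyp2f2 at -10.65 (next -5.46) on array b of mouse 3, Ephx1 at -1.55 (next -2.45) on array d of mouse 1 and Cyp3a11 at -3.31 (next -6.38) on array d of mouse 2.

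Dim probes lay toward liver on all 6 arrays of mouse 2, with medians between -1.72 and -1.45. A single shift of whole arrays is argued against, because the bright probes moved by 0.179 of the move of the dim probes. Lower kidney and higher liver expression in mouse 2 stays open: the dim probes lay within 0.255 of the most frequent log2 value, but 9 of 10 arrays of mice 1 and 3 met the bound of 0.5 too, so the test does not decide. As deposited, the most frequent value was 1.32 to 1.72 on the kidney arrays and -1.44 to -1.26 on the liver arrays of mouse 2. On the other 10 arrays it was at most 0.5645 in size. If it marks equal raw intensities, a normalization factor moved it away from 0 on the arrays of mouse 2. Whether that factor was set apart from the dim probes is left open by the same distance of 0.255. An additive background stays open as well, since raw intensities were not used.

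Differences between mice repeated between their kidney and liver arrays as kidney over liver, although different RNA of the animal enters each kind. Over 2916 bright probes the difference between mice 1 and 3 correlated at 0.504 between both kinds. This restates the repeat on a part of the same probes, with a bound chosen after it was seen. It is therefore no separate test of expression of the animals against constant pools. A change common to both organs would give a negative correlation, which the repeat goes against. Opposite changes in both organs were not tested. RNA shared by both kinds of a mouse number may be a source, but different probes of a gene correlated across kinds at only 0.15 of the correlation of the same probe (71 genes), and at 0.404 and 0.45 for mice 1 and 2 and mice 2 and 3. A batch of prints, slides or dyes that acts probe by probe may be another, with a correlation of 0.0938 between different probes of a gene (95% bootstrap interval -0.153 to 0.266) for mice 1 and 3. With mouse 2 aligned by signal it was 0.27 (0.1 to 0.413) for mice 1 and 2, and for mice 2 and 3 0.344 (0.154 to 0.503), intervals above 0 that go against a batch acting on single probes alone. Both sources, which can act together, cannot be told apart, as the intervals are wide and the labels give no batch.

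Of the 10 splits of the 6 averages into 3 and 3, the real split called 2358 probes between kidney and liver. The highest other called 0. Other splits turn the sign of some averages, which spreads organ differences within a group, and leave out the pairing by mouse. Their 0 calls therefore say nothing about chance. For lists, 2 of 10 called as many as the real 14, the other splits calling 8 to 15. As these keep part of the organ difference, the list counts do not measure chance either. With 10 splits no share under 0.1 can be reached. Of 100 splits of the 9 liver arrays, 1, the real one, called 15870 probes between mice and the highest other 14383, a share under 0.05 for random groups of arrays. As the arrays of a mouse repeat the same RNA, this says nothing about chance between animals. The 5 other splits that kept the arrays of mouse 2 together called 14123 to 14383 and the remaining 94 at most 2, which points to a structure of the samples.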

How the results depend on the processing

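The alignment of mouse 2, the bright probes alone, the blocks on kidney over liver and the blocks for both array kinds were chosen after seeing the data. The number of probes differing between kidney and liver moved from 2358 to 5445 with median-centred arrays, 5830 with arrays scaled to one spread, 13609 with quantile normalization, 4141 with 16 arrays and a random block, 774 on kidney arrays alone, 1543 on liver arrays alone and 6301 with mouse 2 aligned. With the mouse number as a replicate block it was 966 on the scale of sample over pool, 15400 on kidney over liver and 10527 on that scale with mouse 2 aligned. Leaving out a mouse gave 700 (without mouse 1) to 4873 (without mouse 2). The causes were not tested. It stayed within 1.5 times with no filter (2317), probes on all arrays (2313 of 8949), weights (2506), trend and robust variances (2866) and bright probes (2141 of 2967). Of the 2358 probes, 2116 kept their call after centring and 2292 after alignment, and 0 were called in the opposite direction. Between both array kinds, 3 probes passed with one spread, 11 with quantile normalization, 5 with mouse 2 aligned, 1 among bright probes and 3 among the 15703 others. With the mouse number as a replicate block it was 5 on sample over pool, 18 on kidney over liver and 33 on that scale with mouse 2 aligned. It was 0 with centring, with either filter and with a mouse left out, limma finding between 7 and 852 at an unadjusted p under 0.05 in the last. Camera called 14 lists, 13 to 15 in the other settings, but 0 with an estimated correlation (9 at an unadjusted p under 0.05). The block changed no list call on the scale of sample over pool, and phase II conjugation lost its call on kidney over liver (adjusted p 0.121, camera, Benjamini-Hochberg). For the mice on kidney arrays, 10967 became 7115 with centring, 5929 with one spread, 4871 with mouse 2 aligned and 1223 among 2901 bright probes, and 3 (without mouse 2) to 13847 (without mouse 3) with a mouse left out. On liver arrays, 15870 became 7133, 6147, 5850 and 2084 among 2935 bright probes, 10348 among 12118 probes with all values, and 197 (without mouse 2) to 15761 (without mouse 3). Fewer probes were tested in the last sets. For the 103 named genes, 2120 of 2337 values under alternatives kept their call, 217 lost it and 0 changed sign. Between mice, 124 of 137 kept it and 13 lost it. A change of sign was not possible where averages with the same sign were only left out or weighted. Where a mouse left out leaves a single array, it is assumed to vary like the others. Of probes that were not bright 939 of 15703 were called, against 1419 of 2967 bright ones. Lower signal over background, the offset of mouse 2 and the choice of bright probes from the ratios themselves were not separated here.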

Other observations

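Among 10 genes of the circadian clock and its output, Dbp (-3.96, SE 0.28) and Nr1d1 (-3.04, SE 0.20) were higher in liver and Bhlhe40 (2.04, SE 0.23) in kidney (2 and 1 adjusted over the list alone; camera adjusted p 0.899). Among 21 leukocyte genes, Tyrobp (-2.92, SE 0.22), the Kupffer cell receptor Clec4f (-1.91, SE 0.28), Cd79b (-1.22) and C1qa (-1.12) were higher in liver and H2-Aa (0.89) in kidney (7 and 2 adjusted over the list alone; adjusted p 0.944 by camera). After centring 5 leukocyte genes were higher in liver and 5 in kidney, and with mouse 2 aligned by signal 6 and 6. C1qa lost its call after centring (adjusted p 0.0552, limma, Benjamini-Hochberg). Of 15 genes of adipose tissue and muscle, Car3 (-6.99, SE 0.29) and Ucp1 (-2.81, SE 0.28) were higher in liver and Lpl (1.73, SE 0.21) and Fabp4 (1.53, SE 0.25) in kidney (2 and 2 adjusted over the list alone; camera adjusted p 0.807), and after centring 2 in liver and 4 in kidney. Of 10 genes of bile duct and stellate cells, Ecm1 (-1.77) and Sox9 (-1.03) were higher in liver and Cftr (1.37) in kidney (4 and 2 adjusted over the list alone; camera adjusted p 0.944). Of 9 commonly used reference genes, B2m (-3.15, SE 0.20) was higher in liver and Pgk1 (1.12, SE 0.21) in kidney (5 and 1 adjusted over the list alone; camera adjusted p 0.949).

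Of 21 immediate early and stress genes, Hsp90aa1 (-1.44, SE 0.27) was higher in liver and Fkbp5 (0.95, SE 0.25) in kidney (4 and 2 adjusted over the list alone; camera adjusted p 0.497). After centring 1 of them was higher in liver and 6 in kidney, and with mouse 2 aligned 3 and 7. With that alignment Hsp90aa1 was at -0.80, Sox9 at -0.51 and Cd79b at -0.60, each still called. They are dim, with 66.7%, 66.7% and 55.6% recurring values. Car1 (-1.45, SE 0.29) was the call among 4 blood genes (2 in liver and 1 in kidney adjusted over the list alone; camera adjusted p 0.949), and Amy2 (-1.50, SE 0.31) that among 9 genes of pancreas and intestine (1 adjusted over the list alone; camera adjusted p 0.949). Of 7 adrenal cortex genes, limma called 0 (0 adjusted over the list alone; camera adjusted p 0.555). With the mouse number as a replicate block on the scale of sample over pool, Cd79b, H2-Aa, Sox9, Pgk1, Hsp90aa1, Fkbp5 and Amy2 lost their call. Over up to 23 alternatives, H2-Aa and Fkbp5 lost it in 10 each, Sox9 in 8, Cd79b in 7, Amy2 in 5, Pgk1 and Hsp90aa1 in 4 each, Fabp4 in 3, Cftr and Car1 in 2 each and Clec4f in 1.

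The 8 genes with probes called in opposite directions were Calm3 (-0.83 to 1.59), Cndp2 (-1.76 to 3.91), Kifc3 (-1.43 to 1.09), Nrxn2 (-1.73 to 2.17), Scarb2 (-0.99 to 0.93), Slco2b1 (-1.88 to 1.16), St13 (-1.35 to 1.13) and Wwp2 (highest 3.00). They were named after their values were seen. As kidney over liver, arrays of the same mouse and organ correlated across probes at 0.859 to 0.94, those of the same mouse and the other organ at 0.815 to 0.914, and those of mice 1 and 3 in the same organ at 0.798 to 0.857. Mouse 2 correlated with the others in the same organ at 0.651 to 0.783.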
